A study of Pelodiscus sinensis with 8 samples.

How the data were processed

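Interdigital tissue of Chinese soft-shell turtle embryos at stage 19 of the Tokita-Kuratani series was sequenced as 8 pools, 4 forelimb webs and 4 hindlimb webs, each pool holding 40 tissues of the same 20 individuals, per the labels. Per the labels' protocols, total RNA was extracted on columns with DNase treatment, checked on a Bioanalyzer, made into libraries with a NEBNext Ultra RNA kit and sequenced as paired-end Illumina reads. No strand setting was stated, so a gene and an overlapping or antisense neighbour cannot be told apart.

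The authors deposited 2 tables, one of counts per gene and one of TPM per gene with gene symbols. Reads were handled with HISAT2 2.2.1 and StringTie 2.1.7, per the submitters' processing notes. The genome build and annotation were not given in the sources used here, and no coordinates were used. The deposited counts were whole numbers that summed to a different total in each library, and they were not normalised. The deposited TPM values are scaled to gene length and to a fixed total, so they keep no depth. Of 20472 values from 1 to 40 in the count table, 35.5% were multiples of 4, against 25% for an even spread, so a count is not 1 independent read pair and no counting interval is given. Symbols came from the deposited TPM table, and 288 genes that share a symbol with another were kept apart. Of the tested genes 3871 (26.9%) had no symbol.

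Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes passed edgeR's filterByExpr with limb as the group (minimum count 10, minimum total 15), which left 14386 of 19328 genes, and libraries were scaled by TMM with factors of 0.973 to 1.02. CPM values are TMM-scaled. Log2 CPM for principal components and list medians used a prior count of 2. Tests were edgeR's quasi-likelihood tests with Benjamini-Hochberg adjustment at 0.05. The limb comparison had limb as its only term and gives hindlimb minus forelimb. The web comparison had limb and web number from 1 to 4, and gives log2 units per web toward web 4. The interaction added their product. Residual degrees of freedom were 6, 5 and 4. Libraries held 53116512 to 65849337 counts, and the depth limits what can be said of genes near the filter. Standard errors are the log2 fold change divided by the root of the F statistic.

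Libraries of the same web in the 2 limbs share a position and the same animals. Their deviations from the limb means correlated at 0.498, 0.189, 0.242 and 0.327 for webs 1 to 4, each above 0.1, so web number was taken to pair the libraries and the fit with web number as a block is given where it changes a call or a count. Neighbouring webs also passed 0.1, with 0.184 for forelimb web 2 and hindlimb web 1 and 0.237 for forelimb web 3 and hindlimb web 4. For webs 2 and 3 the matched value thus barely exceeded that of a neighbour.

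Before the data were examined, 31 gene lists, the tests, the alternatives and the rule for named genes were set. The lists held limb identity, patterning, signalling, cell death, lysosome, senescence, oxidative stress, protease, cartilage, joint, fibroblast and tendon, muscle, endothelial, erythroid, macrophage, epidermis, apical ridge, nerve, pigment, cell cycle, stress response, glycolysis and mitochondrial genes, matched by symbol. The 29 lists with at least 5 tested members were tested by camera in limma 3.58.1 with a preset correlation of 0.01, again with an estimated correlation, and by fry. The rule named, for the limbs, a fixed set of limb and interdigital genes, up to 8 genes per direction with the largest change among those that passed with a mean of at least 2 CPM, a symbol and no overlap between limbs, and up to 4 passing members of each list, or the 2 most abundant where none passed. For web position it named a fixed set of patterning genes, up to 6 genes per direction with the same sign of slope in each limb, and up to 3 passing members of each list. For the interaction it named up to 4 genes per direction, or the 3 with the lowest p where none passed. The text gives the fullest statistics for part of these genes and a range or count for others, and some genes the rule names are not reported here. HOXA13, TBX3 and the HOXC genes did not stand under a symbol and were not analysed here.

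The edgeR limb, blocked limb, web and interaction tests were tried on simulated counts of 14386 genes with 200 changed by known folds. DESeq2, limma-voom, limma on TPM, fry and the splits and orders of libraries were not tried on simulated counts. The limb test made 0 false calls and the interaction test 1. The web test recovered 43.3%, 70.1% and 83.3% of genes that changed 1.5-fold, 2-fold and 4-fold from web 1 to web 4, with 14 false calls, a share above the nominal 5% of its calls. Its counts were drawn with the spread of the blocked fit and no effect shared by the 2 libraries of a web beyond the simulated slope. The real libraries of a web are paired, so these figures do not show how often the web test calls falsely or misses genes in these data. The blocked limb test recovered 53.7%, 82.1% and 92.4% with 11 false calls, also above 5% of its calls. A cartilage list of 19 genes raised 1.5-fold was called by camera with the preset correlation, and no other list was. Genes were drawn independently there, while estimated correlations within real lists reached 0.63 for cell cycle and 0.92 for erythroid genes between the limbs. That simulation thus does not show how often camera calls a list falsely in these data.

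Alternatives were other scalings (RLE size factors, library size alone), DESeq2 1.42.0, limma-voom, a robust prior, no filter beyond 1 count, a filter of 1 CPM in 4 libraries, limma on log2(TPM + 1) and log2(TPM + 0.1), a minimum log2 change of 1, other codings of web number and each library left out in turn. Alternatives chosen after seeing the data were leaving out web 1 of both limbs and the blocked fit in DESeq2 and limma-voom. No value column was left without a sample.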

Results

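Gene expression was measured in the tissue between the digits of Chinese soft-shell turtle (Pelodiscus sinensis) embryos, an aquatic turtle whose feet are webbed. Embryos were at stage 19 of the Tokita-Kuratani series, which stages embryos of this species. Web 1 lies between digits I and II and web 4 between digits IV and V, and each of the 4 webs of the forelimb and of the hindlimb gave 1 library, 8 in total. Every library pooled 40 pieces of tissue, left and right, from the same 20 individuals. The labels tag the forelimb pools "ICD" and the hindlimb pools "anti-ICD" without spelling the term out. No position had a second pool of other animals, so p-values measure the spread between these pools and say nothing of differences between animals.

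Forelimb webs 1 to 4 held 59093128, 65849337, 54831395 and 56195496 counts, and hindlimb webs 1 to 4 held 53116512, 54888995, 55297039 and 55385613, a ratio of 1.24 between the largest and the smallest. Of 19328 genes in the table, 14386 had enough counts to be tested. Log2 CPM correlated between libraries at 0.955 to 0.981. A symbol was missing for 7598 genes, which took 16.1% of all counts. No gene of the HOXC cluster stood under a symbol, so HOXC10 and HOXC11, which mark the hindlimb in other vertebrates, were not analysed here.

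The first comparison asked how the hindlimb webs differed from the forelimb webs. TBX4 (ENSPSIG00000017594), a transcription factor of the hindlimb, averaged 152 ± 15.3 CPM in the hindlimb and 1.37 ± 1.35 CPM in the forelimb (SD, n = 4 each). TBX5 (ENSPSIG00000018214), its forelimb counterpart, averaged 32.3 ± 2.57 CPM in the forelimb and 0.720 ± 0.204 CPM in the hindlimb. TBX4 rose by a log2 fold change of 6.76 ± 0.585 (SE; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0029) and TBX5 fell by 5.48 ± 0.205 (adjusted p = 1.7e-06). A gene without a symbol, ENSPSIG00000008146, named after its values were seen, fell by 3.72 ± 0.125, from 93.9 ± 5.47 to 7.15 ± 1.13 CPM (adjusted p = 1.3e-06). In all 3 genes the 4 hindlimb libraries lay apart from the 4 forelimb libraries. These were the only genes of 14386 past an adjusted p of 0.05 in edgeR without a block, against 581 at an unadjusted p under 0.05. DESeq2 called 18 genes, 6 higher and 12 lower, and edgeR with web number as a numeric covariate called 5. With a robust prior the TBX4 call ended at an adjusted p of 0.088, in a range of 5.6e-26 to 0.088 over its alternatives.

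**Figure D1:**
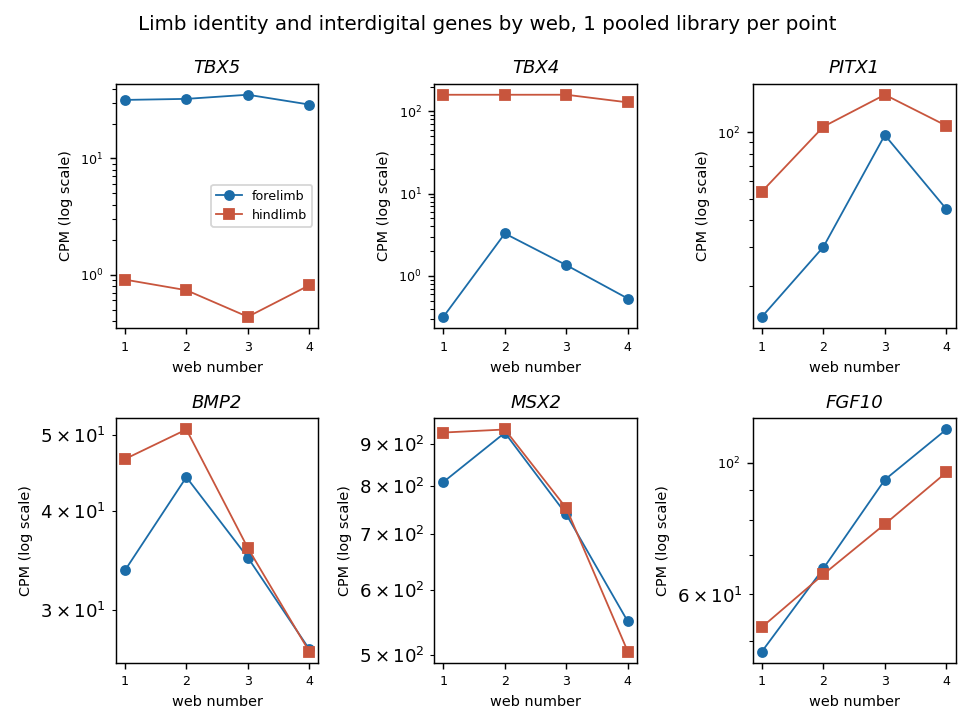
CPM (log scale) against web number for 6 genes, with 1 point per pooled library, blue circles for forelimb and red squares for hindlimb. TBX5 lies between 29.1 and 35.4 CPM in the forelimb and under 1 CPM in the hindlimb, TBX4 lies between 129 and 159 CPM in the hindlimb, and BMP2, MSX2 and FGF10 did not pass the limb test.

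With web number as a block, which compares the limbs within each web, 24 genes passed, 13 higher and 11 lower in the hindlimb, and 17 of them had a symbol. All 3 genes of the unblocked test were among them. PITX1, which acts upstream of TBX4 in the hindlimb, averaged 46.7 ± 35.9 CPM in the forelimb and 104 ± 38.7 CPM in the hindlimb (SD, n = 4 each). Its log2 fold change was 1.38 ± 0.175 with the block (edgeR, adjusted p = 0.014) and 1.16 ± 0.508 without it (adjusted p = 1.0). The remaining symbols given here were chosen after their values were seen. HAND2, a posterior limb factor, rose by 0.57 ± 0.068 (adjusted p = 0.012) and HOXA7 by 0.80 ± 0.106 (adjusted p = 0.016). SFRP2, a secreted Wnt modulator, fell by 0.54 ± 0.0645 (adjusted p = 0.012), and GPNMB, a glycoprotein found in pigment cells and macrophages, fell by 0.94 ± 0.12 (adjusted p = 0.014). The same block gave 146 genes in DESeq2 and 33 in limma-voom. It leaves 3 residual degrees of freedom. In simulated data the edgeR test with the block made 11 false calls, a share above the nominal 5% of its calls. Beside them it recovered 36, 55 and 61 genes changed 1.5-fold, 2-fold and 4-fold.

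Genes that act in interdigital regression in other amniotes did not pass the limb test. The signals BMP2, BMP4 and BMP7 had log2 fold changes of 0.20 ± 0.209, 0.22 ± 0.12 and 0.21 ± 0.326, and the BMP antagonist GREM1 had -0.12 ± 0.214. The BMP-responsive factors MSX1 and MSX2 stood at -0.12 ± 0.288 and 0.05 ± 0.207. FGF10 had -0.14 ± 0.263, the retinoic acid enzymes ALDH1A2 and CYP26B1 had -0.39 ± 0.229 and -0.31 ± 0.389, and the receptor RARB had -0.08 ± 0.136. Each of these had an adjusted p of 1.0 in edgeR without a block, and the sign changed in at least 1 alternative without it for BMP7, GREM1, MSX1, MSX2, FGF10 and RARB. With web number as a block none of the 10 passed (adjusted p 0.29 to 0.94) and none changed sign. BMP7, higher in the hindlimb in each of the 4 webs, stood at 0.25 ± 0.066 (adjusted p = 0.29), and MSX1 and ALDH1A2 were lower there in each of the 4 webs. FGF8, a signal of the apical ridge at the limb tip, was not tested, with 40 counts over all 8 libraries. In data simulated at this design, the test without a block recovered 25.4% of genes changed 1.5-fold, 58.2% of those changed 2-fold and 77.3% of those changed 4-fold, so most differences of 1.5-fold would have been missed by it. The test with the block recovered 53.7% of genes changed 1.5-fold.

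Among the lists of genes, the hindlimb identity list had 1 member that rose (TBX4) and 2 that did not pass, and the forelimb identity list had 1 member, TBX5, which fell. Without a block, no member of any other list passed over all genes tested in edgeR, and adjusted over the list alone only pigment cell and erythroid members did. Camera with a preset correlation called 4 of 29 lists, and none of the 29 held with an estimated correlation. Pigment cell genes ranked lower in the hindlimb (camera adjusted p = 1.2e-09, and adjusted p = 0.17 with an estimated correlation), with negative values in 9 of 10 members. For the 10 members, 4 were lower when adjusted over the list alone and 0 over all genes. TYR, the rate-limiting enzyme of melanin synthesis, and the receptor KIT, both named after their values were seen, had log2 fold changes of -1.02 ± 0.218 and -0.70 ± 0.148 (adjusted p = 0.86 each), and TYRP1 had -0.15. Erythroid genes ranked lower too (camera adjusted p = 2.8e-08, and adjusted p = 0.43 with an estimated correlation), with 5 of 5 members negative and 3 lower when adjusted over the list alone. The globin HBZ averaged 1690 CPM in the forelimb and 917 CPM in the hindlimb, a log2 fold change of -0.88 (adjusted p = 1.0). By library, the erythroid median lay at 0.15, 0.61, -0.11 and 0.83 in forelimb webs 1 to 4 and at 0.21, -0.40, -0.39 and -0.89 in hindlimb webs 1 to 4 (log2, against the mean of the 8).

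Cell cycle genes ranked higher in the hindlimb (camera adjusted p = 2.0e-06, and adjusted p = 0.72 with an estimated correlation), with positive values in 20 of 21 members and 0 passing when adjusted over the list alone, against 4 higher with web number as a block. PCNA had a log2 fold change of 0.15 and KIF11 of 0.12. Fibroblast and tendon genes ranked lower (camera adjusted p = 0.012, and adjusted p = 0.72 with an estimated correlation), with 18 of 22 members negative and 0 passing when adjusted over the list alone, against 3 lower with web number as a block. COL1A2 and COL3A1 had -0.12 and -0.16. That call ended without forelimb web 2, forelimb web 3, hindlimb web 1 or hindlimb web 2, at adjusted p values of 0.085 to 0.27. The count of lists was 8 without forelimb web 1, 7 without hindlimb web 3 and 7 without hindlimb web 4. With web number as a block, epidermis genes (adjusted p = 0.0043, and adjusted p = 0.65 with an estimated correlation) and Wnt signalling genes (adjusted p = 0.029, and adjusted p = 0.52 with an estimated correlation) also ranked lower. Over all genes, the block added PITX1 of the hindlimb identity list, HAND2 of the posterior list and SFRP2 of the Wnt list. Adjusted over the list alone, it gave 3 lower members each for the Wnt and joint lists, 2 for epidermis, 1 higher and 2 lower for FGF signalling, and 5 lower for pigment cells. Single members passed that way in the posterior list (higher) and in the apical ridge, nerve, oxidative stress and immediate early lists (lower), and 1 in each direction in the anterior and BMP lists. With the block, directional fry called pigment cell genes (adjusted p = 0.047, against 0.16 without it), and mixed fry called 9 lists, against 1. Without the block, pro-apoptotic genes (18 members) and anti-apoptotic genes (8 members) had camera adjusted p values of 0.29 and 0.80, with 0 members passing. The other lists, of patterning and signalling genes, lysosome, senescence, oxidative stress, protease, cartilage, joint, muscle, endothelial, macrophage, apical ridge, nerve, stress response, glycolysis and mitochondrial genes, had camera adjusted p values of 0.12 to 0.94 without the block, with 0 members passing. Of these, camera called senescence genes without forelimb web 1 or hindlimb web 3 (adjusted p 0.0038 to 0.038) and matrix proteases without forelimb web 1, forelimb web 4 or hindlimb web 4 (0.01 to 0.021). It called macrophage genes without forelimb web 1 or hindlimb web 3 (0.00029 to 0.028), endothelial genes without forelimb web 2 or hindlimb web 4 (0.0043 to 0.0082), skeletal muscle genes without hindlimb web 1 (0.00069) and epidermis genes without forelimb web 3 (0.013). Mitochondrial genes were called without forelimb web 1, forelimb web 2, hindlimb web 3 or hindlimb web 4 (3e-04 to 0.038).

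The second comparison followed expression from web 1 on the digit I side to web 4 on the digit V side. Web position was the leading difference among the libraries: the first principal component took 36% of the variance and ran from -49.4 to 28.5 over forelimb webs 1 to 4 and from -43.7 to 45.7 over hindlimb webs 1 to 4. The third component, with 13% of the variance, was negative in the 4 forelimb libraries and positive in the 4 hindlimb libraries. A slope with web number passed for 1600 of 14386 genes, 644 rising and 956 falling toward web 4, and 693 of these changed at least 2-fold from web 1 to web 4 (edgeR, limb as covariate). The fit counts the 2 libraries of a web as independent, although they share a position and animals, so its p-values may be too small. With webs 3 and 4 exchanged in both limbs, 882 genes still passed. Across genes, which are not independent replicates, the slopes of the 2 limbs fitted apart correlated at 0.544. Of the 24 orders of the hindlimb webs none gave as high a value (exact permutation p = 0.0417, one-sided, the smallest possible; highest other 0.525). The forelimb alone gave 305 genes and the hindlimb alone 1076, and all 247 genes in both had the same direction. The count was 1014 without forelimb web 1, 875 without hindlimb web 1 and 681 without web 1 of both limbs, a choice made after seeing the data. Scaling by library size alone gave 485 rising and 1122 falling genes, log2(TPM + 1) gave 377 and 1059 (310 and 902 without the count filter), and log2(TPM + 0.1) gave 370 and 1038.

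**Figure D2:**
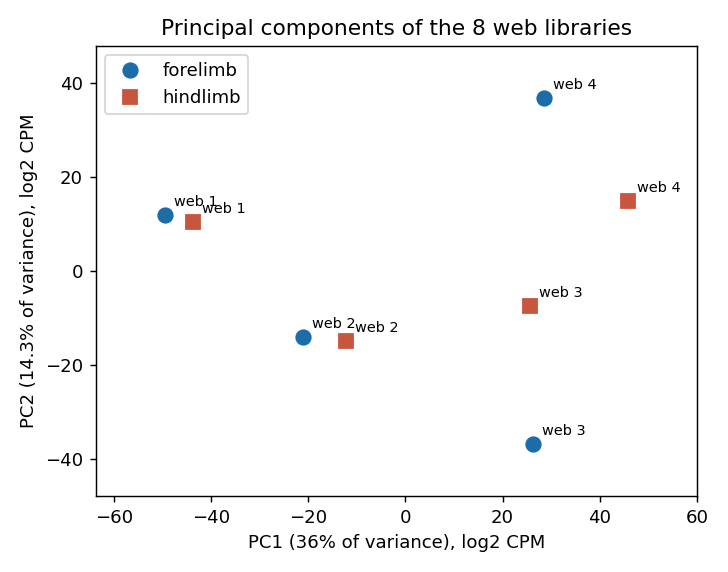
First and second principal components of log2 CPM over 14386 genes, with blue circles for forelimb and red squares for hindlimb and 1 point per pooled library. The axes give each component's share of the variance (36% and 14.3%), and in both limbs web 1 lies at the low end of the first component and web 4 at the high end.

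Part of the genes that pattern the limb from digit I to digit V followed web position. HOXD11 rose from 0.276 CPM in web 1 to 31.3 CPM in web 4 (means of the 2 limbs), with a slope of 1.97 ± 0.317 log2 units per web (edgeR, adjusted p = 0.0023). HOXD10 rose with a slope of 1.08 ± 0.122 (adjusted p = 0.00028) and HOXD12 with 0.63 ± 0.111 (adjusted p = 0.0041), while HOXD13 had 0.10 ± 0.036 and did not pass (adjusted p = 0.12). Of the 7 measured genes of the 5' HoxA and HoxD list, 3 rose and 4 did not pass, and 6 rose when adjusted over the list alone (camera adjusted p = 9.0e-06, and adjusted p = 0.29 with an estimated correlation). Among posterior limb bud genes, HAND2 rose from 13.1 to 89.3 CPM (slope 0.93 ± 0.0858, adjusted p = 9.1e-05), TBX2 rose from 27.6 to 93.2 CPM (0.58 ± 0.0381, adjusted p = 1.6e-05) and SALL1 fell (-0.50 ± 0.0786, adjusted p = 0.002). The other 5 of its 8 members did not pass, PTCH1 (-0.07, adjusted p = 0.59) and GREM1 (0.20, adjusted p = 0.11) among them, and adjusted over the list alone 3 rose and 2 fell. GREM1 passed without forelimb web 4 (adjusted p = 0.021). Camera called that list higher (adjusted p = 0.015, and adjusted p = 0.29 with an estimated correlation), and the call ended without forelimb web 1 (adjusted p = 0.1). SHH had 0 counts in all 8 libraries. Of 7 anterior limb bud genes 2 fell, ALX4 among them (-0.62 ± 0.146, adjusted p = 0.018), IRX5 (0.20 ± 0.0341) and PAX9 (0.23 ± 0.0591, adjusted p = 0.029) rose, and 3 did not pass (3 rose and 2 fell when adjusted over the list alone; camera adjusted p = 0.94). PAX9 lost its call without forelimb web 1, forelimb web 4, hindlimb web 1 or hindlimb web 4 (adjusted p 0.067 to 0.15), and ALX4 without forelimb web 1, forelimb web 4 or hindlimb web 4 (0.052 to 0.12).

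**Figure D3:**
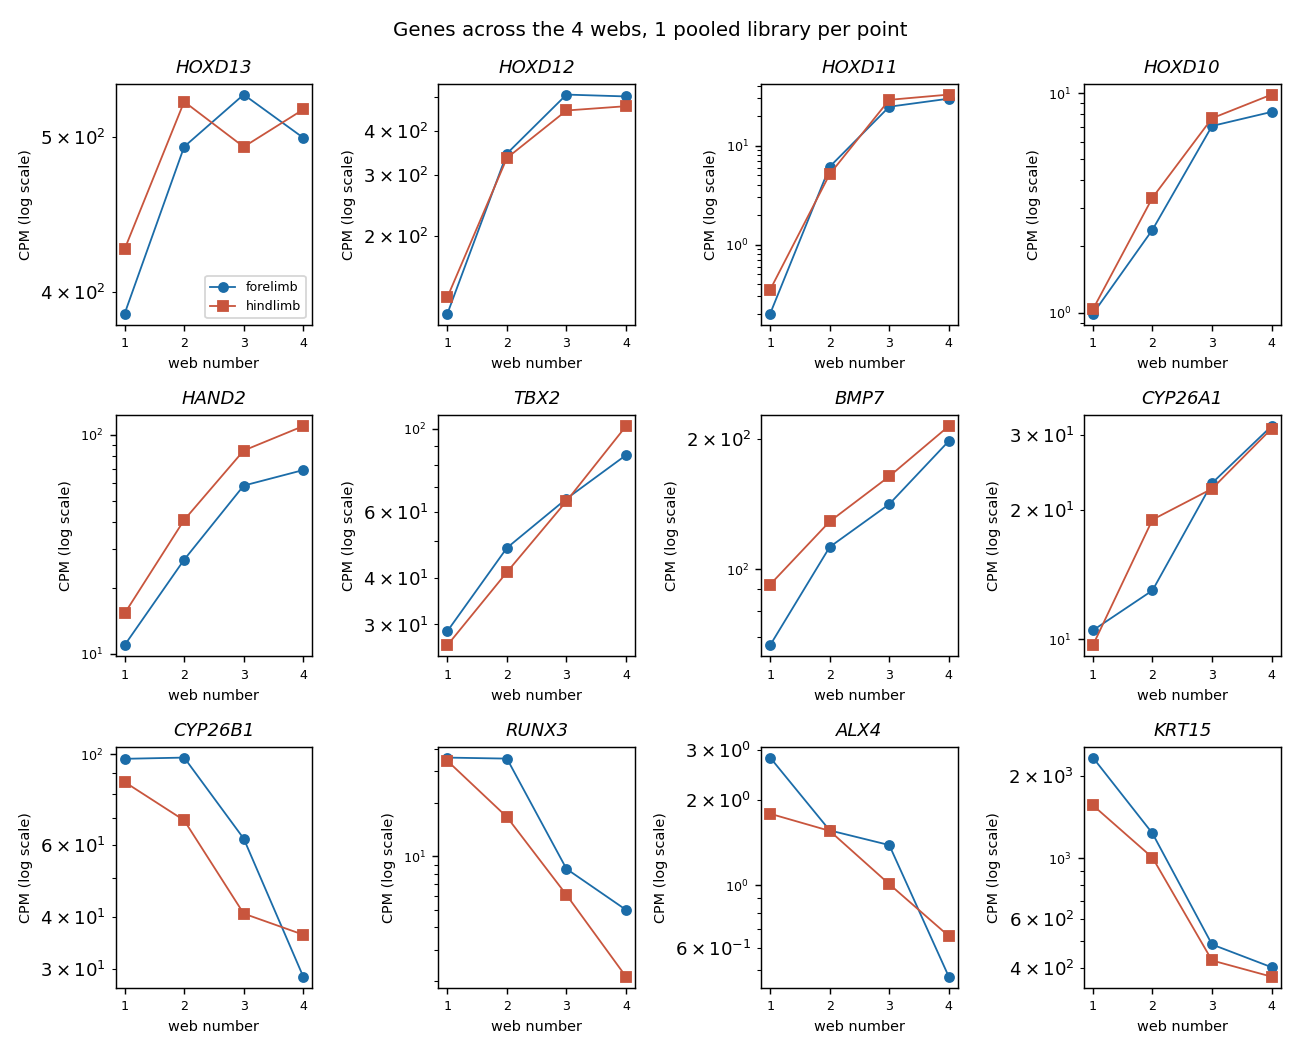
CPM (log scale) against web number for 12 genes, with 1 point per pooled library, blue circles for forelimb and red squares for hindlimb. HOXD11, HOXD10, HAND2, TBX2, BMP7 and CYP26A1 rise toward web 4 in both limbs, CYP26B1, RUNX3, ALX4 and KRT15 fall, and HOXD13, which did not pass, ends at a mean of 510 CPM from 407 CPM.

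Among genes with a symbol and outside the HOX genes, steep slopes belonged to genes of varied function. SP9, a transcription factor of the apical ridge, rose from 0.0704 to 9.39 CPM (slope 2.101 ± 0.174, adjusted p = 4.1e-05), and PHEX, an endopeptidase of phosphate balance, rose from 10.9 to 150 CPM (1.37 ± 0.163, adjusted p = 0.00038). GABRR2, BPIFC and P2RY6 rose with slopes of 1.31, 1.31 and 1.12. MSLN fell from 41.8 to 1.3 CPM (-1.88 ± 0.195, adjusted p = 0.00019), the calcium-binding protein CALB1 fell from 16 to 0.707 CPM (-1.70 ± 0.316, adjusted p = 0.0054), and FADS6, FSTL4 and SEZ6L fell with slopes of -1.655, -1.34 and -1.34. ND4L, a mitochondrial gene that overlaps ND4 so that reads between them may be split, was nearly absent in 4 libraries rather than graded. It stood at 90.8, 77.4, 51.1 and 0.0366 CPM in forelimb webs 1 to 4 and at 116, 0.0367, 0.0361 and 0.0368 CPM in hindlimb webs 1 to 4, while ND4 stood at 396 to 897 CPM. Its slope of -2.92 ± 0.727 (adjusted p = 0.025) thus does not measure a gradient, and its call ended without hindlimb web 1, hindlimb web 3 or hindlimb web 4 (adjusted p 0.077 to 0.25).

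Signalling genes were graded in both directions. BMP7 rose from 79.6 to 206 CPM (slope 0.45 ± 0.0332, adjusted p = 2.6e-05), while BMP5 (-0.34 ± 0.0488) and the BMP target ID4 (-0.27 ± 0.0365) fell. Of 16 BMP ligands, receptors and targets, 2 rose, 5 fell and 9 did not pass (2 rose and 7 fell when adjusted over the list alone; camera adjusted p = 0.14, reaching 0.03 without forelimb web 1 and 0.049 without hindlimb web 1). Of 11 BMP antagonists 1 rose (TWSG1, 0.15) and 2 fell, FST (-0.60 ± 0.107, adjusted p = 0.0041) and NOG (-0.58), with 4 rising and 2 falling when adjusted over the list alone (camera adjusted p = 0.55). The NOG call ended in 7 of the 8 leave-outs, all but that of forelimb web 4 (adjusted p 0.052 to 0.15), and the TWSG1 call without forelimb web 1 or hindlimb web 1 (0.06 to 0.066). In FGF signalling 4 of 16 members rose, 1 fell and 11 did not pass (7 rose and 1 fell when adjusted over the list alone). FGF10 rose from 50.5 to 105 CPM (0.35 ± 0.0334, adjusted p = 0.00011), SPRY1 rose (0.20 ± 0.04) and FGFR3 fell (-0.32 ± 0.0461). Camera called that list higher (adjusted p = 0.022, and adjusted p = 0.29 with an estimated correlation), except without forelimb web 1 (adjusted p = 0.068). The enzymes that degrade retinoic acid split, with CYP26A1 (0.54 ± 0.0527, adjusted p = 0.00013) and CYP26C1 (0.71 ± 0.0816, adjusted p = 0.0003) rising and CYP26B1 falling from 91.6 to 32.5 CPM (-0.51 ± 0.0702, adjusted p = 0.0009). Of 15 retinoic acid pathway genes 3 rose, 4 fell and 8 did not pass, the same counts as when adjusted over the list alone (camera adjusted p = 0.98). Of 23 Wnt signalling genes 8 rose, 6 fell and 9 did not pass (8 rose and 8 fell when adjusted over the list alone; camera adjusted p = 0.76), with WNT11 (-0.46), SFRP2 (-0.73) and DKK3 (-0.42) among those that fell.

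In the apical ridge and epidermis lists more genes fell than rose toward web 4, while SP9, an apical ridge factor outside these lists, rose (slope 2.101 ± 0.174). Of 9 apical ridge genes 5 fell and 4 did not pass, with 5 when adjusted over the list alone (camera adjusted p = 7.0e-10, and adjusted p = 0.29 with an estimated correlation), and DLX6 (-0.69 ± 0.0529), DLX5 (-0.45 ± 0.0443) and DLX2 (-0.54 ± 0.0565) each fell. The DLX genes are also expressed in other limb tissue. Of 17 epidermis genes 7 fell, 2 rose and 8 did not pass, and adjusted over the list alone 8 fell and 3 rose (camera adjusted p = 4.7e-06, and adjusted p = 0.50 with an estimated correlation). KRT15, a keratin of basal epidermis, fell from 1940 to 386 CPM (-0.81 ± 0.0665, adjusted p = 3.7e-05), LAMB3 fell (-0.73 ± 0.0548) and GRHL3 fell (-0.63 ± 0.0669). The members that rose, named after their values were seen, were the epidermal factor TP63 (0.22 ± 0.0477, adjusted p = 0.014) and TFAP2A (0.14 ± 0.0359, adjusted p = 0.025). Immune cell genes fell in 6 of 14 macrophage and leukocyte members, CSF1R (-0.38 ± 0.0694) and CD74 (-0.33 ± 0.0578) among them, with 8 not passing, and in 9 when adjusted over the list alone (camera adjusted p = 0.00013, and adjusted p = 0.50 with an estimated correlation). ITGB2 also fell (-0.47, adjusted p = 0.0092), except without forelimb web 1 (adjusted p = 0.066). The macrophage median was 0.66, 0.083, -0.54 and -0.28 in forelimb webs 1 to 4. In hindlimb webs 1 to 4 it was 0.48, 0.125, -0.31 and -0.08, so in each limb it was lowest in web 3.

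Mitochondrial genome genes fell in 9 of 13 members, with 4 not passing, and in 11 when adjusted over the list alone (camera adjusted p = 7.4e-08, and adjusted p = 0.29 with an estimated correlation), with slopes of -0.36 for ND1 and -0.28 for COX3 and ND2. The 9 include ND4L, whose slope does not measure a gradient. The median slope of the 13 was -0.278, against a mean of -0.467. Mitochondrial genome genes took 1.32%, 1.2%, 0.758% and 0.863% of counts in forelimb webs 1 to 4 and 1.61%, 0.986%, 0.859% and 0.697% in hindlimb webs 1 to 4. Of 18 skeletal muscle genes 1 fell, NEB (-0.64 ± 0.158, adjusted p = 0.025), and 17 did not pass, with 1 when adjusted over the list alone (camera adjusted p = 0.0017, and adjusted p = 0.60 with an estimated correlation). Without hindlimb web 1 the muscle list was not called (adjusted p = 0.13), and NEB lost its call without forelimb web 1, hindlimb web 1, hindlimb web 3 or hindlimb web 4 (adjusted p 0.051 to 0.2). The muscle median lay at 0.81, -0.19, -1.23 and 0.49 in forelimb webs 1 to 4 and at 1.46, -0.20, -0.16 and -0.93 in hindlimb webs 1 to 4. Of 12 endothelial genes 3 fell, PECAM1 (-0.28), CDH5 (-0.24) and SOX18 (-0.18), and 9 did not pass, with 3 when adjusted over the list alone (camera adjusted p = 0.015, and adjusted p = 0.58 with an estimated correlation). That list lost its call without forelimb web 4 or hindlimb web 4 (adjusted p 0.066 to 0.25). PECAM1 lost its call in all leave-outs but that of forelimb web 2 (0.059 to 0.13), CDH5 without forelimb web 4 or any hindlimb web (0.067 to 0.19), and SOX18 without forelimb web 2, forelimb web 4 or any hindlimb web (0.072 to 0.2). Of 13 nerve and Schwann cell genes 2 fell, SOX10 among them (-0.29 ± 0.0493), and 11 did not pass, with 3 when adjusted over the list alone (camera adjusted p = 0.045, and adjusted p = 0.29 with an estimated correlation). The nerve call ended without forelimb web 1, forelimb web 4, hindlimb web 2 or hindlimb web 4 (adjusted p 0.051 to 0.11). Of 10 pigment cell genes EDNRB (-0.41 ± 0.0536) and DCT (-0.57 ± 0.102) fell and 8 did not pass, with 3 falling when adjusted over the list alone (camera adjusted p = 0.065, and 0.018 without hindlimb web 1 and 0.044 without hindlimb web 3). Erythroid genes had 0 of 5 members passing in edgeR, over all genes or adjusted over the list alone (camera adjusted p = 0.48, and 0.0057 without forelimb web 4). HBZ (-0.07) and TFRC (-0.09) passed without forelimb web 4 (adjusted p = 0.031 and 0.027).

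**Figure D4:**
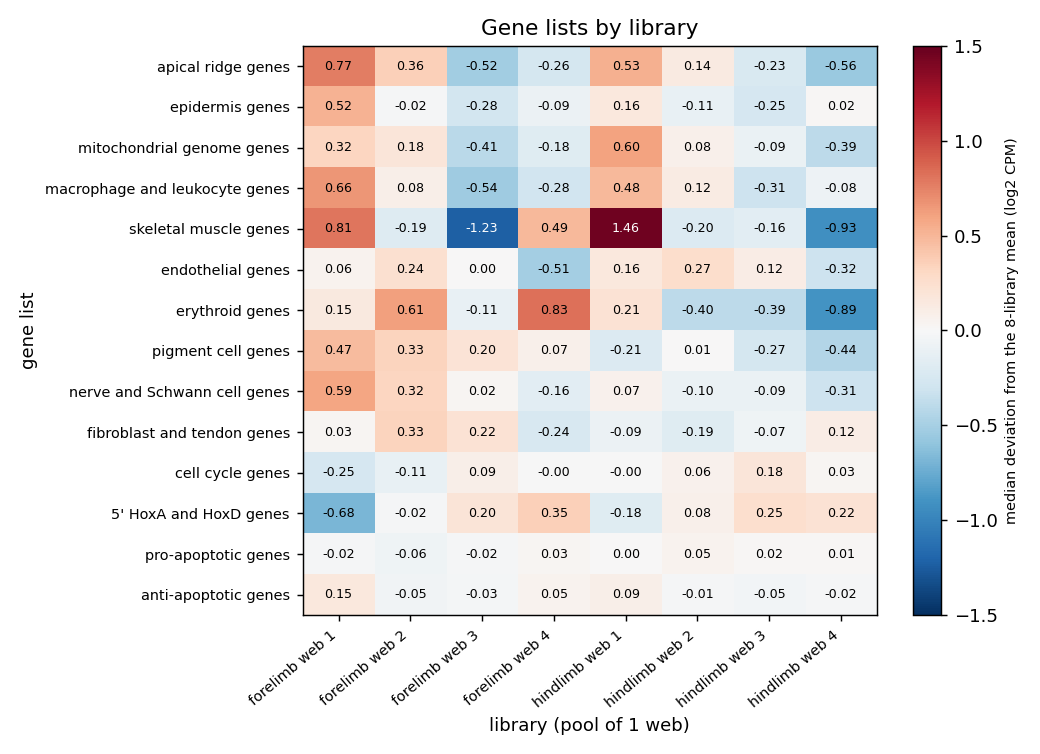
Median over each list's genes of the deviation from the mean of the 8 libraries (log2 CPM, color scale and printed values), with 14 lists as the vertical axis and the 8 pooled libraries as the horizontal axis. The apical ridge and macrophage lists are highest in web 1 of each limb, and skeletal muscle genes reach 1.46 in hindlimb web 1 and -1.23 in forelimb web 3.

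Connective tissue and skeletal genes changed in part. Of 22 fibroblast and tendon genes 5 rose, 2 fell and 15 did not pass (5 rose and 3 fell when adjusted over the list alone). LUM, a proteoglycan of collagen fibrils, rose from 353 to 1330 CPM (0.67 ± 0.0523, adjusted p = 2.7e-05), KERA rose (0.55 ± 0.0323) and COL14A1 rose (0.36 ± 0.0382). Camera called that list higher (adjusted p = 0.020, and adjusted p = 0.60 with an estimated correlation) although its mean slope was -0.04, and the call ended without forelimb web 1 or hindlimb web 4 (adjusted p 0.068 to 0.31). Of 19 cartilage genes 4 fell, 1 rose and 14 did not pass (5 fell and 1 rose when adjusted over the list alone; camera adjusted p = 0.039, and adjusted p = 0.60 with an estimated correlation). RUNX3 fell from 35.1 to 3.56 CPM (-1.21 ± 0.111, adjusted p = 9.0e-05), RUNX2 fell (-0.46 ± 0.0922) and COL2A1, the main cartilage collagen, rose (0.19 ± 0.0415). The cartilage call ended without forelimb web 3, forelimb web 4, hindlimb web 1 or hindlimb web 4 (adjusted p 0.055 to 0.13), and that of COL2A1 without hindlimb web 4 (0.066). Of 10 joint interzone genes 2 rose, 4 fell and 4 did not pass, the same counts as when adjusted over the list alone, with ERG at 0.37, ENPP2 at 0.35 and WNT9A at -0.69 (camera adjusted p = 0.70). Of 18 matrix proteases and inhibitors 3 rose, 1 fell and 14 did not pass (4 rose and 2 fell when adjusted over the list alone; camera adjusted p = 0.62), with MMP16 at -0.35, MMP2 rising from 3050 to 4680 CPM (0.20 ± 0.0403) and TIMP3 at 0.28. MMP2 lost its call without forelimb web 1, hindlimb web 1 or hindlimb web 4 (adjusted p 0.052 to 0.07) and TIMP3 without hindlimb web 1 (0.056).

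Of 18 pro-apoptotic genes 2 fell, BMF (-0.36 ± 0.0402, adjusted p = 0.00026) and PDCD4 (-0.23 ± 0.0456, adjusted p = 0.0078), and 16 did not pass, with 5 falling and 2 rising when adjusted over the list alone (camera adjusted p = 0.62). PDCD4 lost its call without forelimb web 1 (adjusted p = 0.054). Of 8 anti-apoptotic genes none passed in edgeR over all genes, with 1 rising and 1 falling when adjusted over the list alone (camera adjusted p = 0.76), and BAG1 and XIAP had slopes of -0.05 and -0.07. Of 21 cell cycle genes 4 rose, 17 did not pass and 5 rose when adjusted over the list alone, among them MCM6 (0.14), MCM5 (0.13) and PCNA (0.11). Camera called that list higher (adjusted p = 0.0019, and adjusted p = 0.60 with an estimated correlation), except without forelimb web 1 (adjusted p = 0.059). MCM6 lost its call without forelimb web 1 (0.062), and MCM5 (0.11 to 0.12) and PCNA (0.054 to 0.13) without forelimb web 1 or hindlimb web 1. Of 17 lysosome genes 2 fell, CTSK among them (-0.26), and 15 did not pass, with 2 when adjusted over the list alone (camera adjusted p = 0.14, and 0.0081 without hindlimb web 4). Of 14 senescence genes 1 rose (LMNB1, 0.10) and 1 fell (GADD45G, -0.59) and 12 did not pass, the same counts as when adjusted over the list alone (camera adjusted p = 0.48). LMNB1 lost its call without forelimb web 1 or any hindlimb web (0.058 to 0.13).

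Of 21 oxidative stress genes 2 rose, 5 fell and 14 did not pass (2 rose and 6 fell when adjusted over the list alone; camera adjusted p = 0.67), with NFE2L2 (-0.20) and GCLC (-0.25) falling and PRDX2 rising (0.14), the last except without hindlimb web 4 (adjusted p = 0.093). Of 19 immediate early and heat shock genes 4 fell and 15 did not pass (5 fell and 1 rose when adjusted over the list alone), FOSL2 (-0.45), JUNB (-0.29) and ATF3 (-0.28) among them. Camera called that list lower (adjusted p = 0.019, and adjusted p = 0.50 with an estimated correlation), except without forelimb web 1 (adjusted p = 0.068). Of 17 hypoxia and glycolysis genes 4 rose and 13 did not pass (7 rose and 2 fell when adjusted over the list alone; camera adjusted p = 0.14), with LDHA at 0.15, P4HA1 at 0.16 and ENO1 at 0.11. P4HA1 lost its call without hindlimb web 1 or hindlimb web 4 (0.082 each) and ENO1 without forelimb web 1, hindlimb web 1 or hindlimb web 4 (0.069 to 0.085). TBX4, PITX1 and TBX5 did not follow web position by the test (adjusted p = 0.76, 0.096 and 0.70), although PITX1, at a mean of 34.2 CPM in web 1 and 76 CPM in web 4, passed without forelimb web 3 or forelimb web 4 (0.02 to 0.036). In all, camera with a preset correlation called 14 of 29 lists, 5 higher and 9 lower toward web 4, and none with an estimated correlation. The count was 9 without forelimb web 1. fry, which compares a list with no other genes, called 7 lists in 1 direction and 27 as changed in either direction.

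The third comparison asked whether the slope with web position differed between the limbs. No gene did at an adjusted p of 0.05 in edgeR, with 558 at an unadjusted p under 0.05, 1 gene by DESeq2 and 0 by limma-voom. The genes with the lowest p values in each direction, among those with a symbol and a mean of at least 2 CPM, did not pass. With the higher slope in the hindlimb these were PNKD (difference in slope 0.64 ± 0.144), AHNAK (0.29 ± 0.0653) and TYR (0.49 ± 0.117). The muscle genes KLHL40 (-1.40 ± 0.305) and TNNT1 (-1.02 ± 0.225) and SYT14 (-0.83 ± 0.184) went the other way, each of the 6 with an adjusted p of 1.0. Without forelimb web 1 there was 1 gene and without forelimb web 4 there were 2. In data simulated at this design the test recovered 0% of genes whose slopes differed by 1.5-fold between the limbs over the webs, 4.48% at 2-fold and 53% at 4-fold, so most differences of 2-fold would have been missed.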

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

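The tests of the difference in slope between limbs for gene lists, of the orders that keep the web pairs, of the share of epidermis, of skin and of pigment cells were chosen only after the result was seen.

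TBX4 stood at 129 CPM in hindlimb web 4, while hindlimb webs 1 to 3 all stood at 159 CPM. It was the 1 value standing apart in 88 groups of 4 libraries tested, where chance gives about 5%, and the TBX4 call stayed when hindlimb web 4 was left out.

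Several lists had slopes that differed between the limbs by camera with a preset correlation. Adjusted p values were 3e-11 for skeletal muscle, 3.3e-09 for erythroid, 0.00011 for epidermis, 0.00023 for cell cycle, 0.00094 for fibroblast and tendon, 0.0085 for lysosome, 0.012 for matrix protease, 0.024 for 5' HoxA and HoxD, and 0.027 for macrophage genes. With an estimated correlation 0 of 29 lists were called, the lowest adjusted p being 0.75.

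Web position gave 1600 genes. Removing each library's trend with gene length left 2465 genes, 1437 shared, more than 1.5 times the original count, which argues against gene length bias as the cause. Thinning every library to 53116512 counts left 1606 genes, 1571 of them shared. The totals differed by a ratio of only 1.24 before thinning, so few calls could end by it and it does not decide on library size. Of 100 orders of the webs drawn within each limb, 1, the real one, gave as many genes (highest other 197) and 1 as many lists (real 14, highest other 13), but these orders break the pairs of webs. The orders that keep the pairs number 12, too few for a share under 0.05 (1 gave as many genes, highest other 882 with webs 3 and 4 exchanged, and 1 as many lists, highest other 13). With an estimated correlation 0 lists held, and 9 were called without forelimb web 1. Position, dissection and cell makeup change together along the webs and stay open.

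Of 17 epidermis genes, 7 fell from web 1 to web 4. The list median did not fall steadily, at 0.517, -0.0184, -0.281 and -0.0878 in forelimb webs 1 to 4. In hindlimb webs 1 to 4 it stood at 0.157, -0.111, -0.249 and 0.0214. In each limb it was highest in web 1 and lowest in web 3. With a smaller share of epidermis in the tissue towards web 4 as the whole cause, every member would fall by about the same slope. Instead 2 members, TP63 and TFAP2A, rose past an adjusted p of 0.05. TFAP2A is also expressed outside epidermis, and neither call was followed through the alternatives. The rule of 2 rising members was set after the values were seen, so a smaller share of epidermis stays open. A change in the state of the epidermis was not tested and stays open too.

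Pigment cell genes ranked lower in the hindlimb by camera with a preset correlation, with a median log2 fold change of -0.59, and the call was lost at an adjusted p of 0.17 with an estimated correlation. More skin in the forelimb tissue as the whole cause would lower epidermis genes in the hindlimb alike. Their median was -0.121 with an SD of 0.2, above the pigment cell median by 0.471. That goes against more skin as the whole cause, but the rule was set after the values were seen and does not settle it. The epidermis list also changed direction between the limbs without forelimb web 1 (camera adjusted p = 0.64). As part of the cause more skin stays open, since 14 of 17 epidermis members had negative values. With web number as a block, camera called the epidermis list lower (adjusted p = 0.0043, and adjusted p = 0.65 with an estimated correlation). Fewer pigment cells would lower all pigment cell members about equally. With web number as a block, 3 of 10 members (MITF, TYRP1 and EDNRB) lay further from the list median of -0.58 than their 95% intervals, and without the block 2 did, EDNRB standing at -0.19 ± 0.318 (SE). MITF and EDNRB are also expressed by other cells, so fewer pigment cells stay open, as does a difference in their state, which was not tested. Of 35 splits of the libraries, 30 gave as many lists (real 4, highest other 14), so chance cannot be excluded for the list count.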

How the results depend on the processing

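Tests chosen only after the result was seen were those without web 1 of both limbs and the blocked fits in DESeq2 and limma-voom. The limb count of 3 moved to 18 with DESeq2, 5 with web number as a numeric covariate, 24 with web number as a replicate block, 146 with DESeq2 and the block and 33 with limma-voom and the block. The web count of 1600 moved to 693 with a minimum 2-fold change, 681 without web 1 of both limbs, 0 for web 1 against webs 2 to 4 (2952 at an unadjusted p under 0.05), 14 for web 4 against webs 1 to 3 and 305 in the forelimb alone. The interaction count of 0 moved to 1 with DESeq2. List counts moved from 4 to 0 with an estimated correlation, 0 with directional fry and 1 with mixed fry for the limbs, and from 14 to 0, 7 and 27 for web position. Leaving out each library in turn gave 3 to 4 genes for the limbs, 875 to 1889 for web position, 0 to 2 for the interaction, 3 to 8 lists for the limbs and 9 to 15 for web position. The minimum fold change and the single-limb fit keep fewer genes or libraries by construction, and for the others the cause was not tested. In edgeR the block changed no other camera call, and no other call among the limb genes that the naming rule gives, than those given with the limb comparison. DESeq2 with the block also called KRT15, ENPP2, OSR2, TFRC and GJA1 lower (adjusted p 0.0014 to 0.012). Of the named genes that passed, 0 changed sign in any alternative, while 34 of 69 named limb genes and 6 of 10 named web genes that did not pass changed sign in at least 1 (TBX2 between the limbs from -0.37 to 0.30). Of 2 named limb genes that passed, 1 (TBX5) kept its call in all alternatives, and of 86 named web genes that passed, 0 did, since web 1 against the rest called none. Of 35 splits of the 8 libraries, 2 gave as many genes as the real 3 (highest other 1051, from a split that parted 0 web pairs), so chance cannot be excluded by that count, and a split of this size points to web position as a structure of the samples. Among the 8 splits that part all web pairs, the other 7 gave at most 0 genes. With the block, 1 of those 8 splits, the real one, gave as many (24, highest other 0), and 8 splits are too few for a share under 0.05. For the interaction the real count is 0, which all 35 splits must reach (highest other 38), so that comparison says nothing of chance; at an unadjusted p under 0.05, 22 of the 35 gave as many genes as the real 558 (highest other 1872). Depth of 53116512 to 65849337 counts limits what can be said of low genes. FGF8 had 40 counts over all 8 libraries and SHH had 0, and whether depth or a lack of expression accounts for this was not tested.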

Other observations

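The genes in this part were chosen after their values were seen, from the 8 in each direction with the lowest p among genes that the naming rule left out. Toward web 4, OTOR, a secreted protein of cartilage and ear, rose from 120 to 886 CPM (slope 1.00 ± 0.0537, edgeR adjusted p = 8.5e-06). The Notch ligand DNER rose from 16.2 to 87.2 CPM (0.85 ± 0.0498, adjusted p = 8.5e-06), the adhesion protein CNTN5 from 10.6 to 80 CPM (1.01 ± 0.0711), the integrin subunit ITGA8 from 96.3 to 199 CPM (0.35 ± 0.024) and the semaphorin SEMA3D from 38.5 to 131 CPM (0.62 ± 0.0459). Toward web 4, LHX9, a LIM homeobox factor of the limb bud, fell from 196 to 18.3 CPM (-1.18 ± 0.106, adjusted p = 7.5e-05). The epidermal differentiation factor ZNF750 fell from 99.5 to 19.6 CPM (-0.81 ± 0.0535, adjusted p = 1.6e-05), the amino acid transporter SLC7A10 from 290 to 66.7 CPM (-0.73 ± 0.0472) and the guidance receptor ROBO2 from 99.5 to 37 CPM (-0.46 ± 0.0352).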
